A study of Mus musculus with 5 samples.

How the data were processed

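DNA methylation was measured by extended reduced representation bisulfite sequencing in 5 libraries of LSK cells from mouse bone marrow, 3 from Idh1-R132H knock-in and 2 from wild-type mice. LSK cells lack the markers of mature lineages and carry Sca1 and Kit, a fraction that holds blood stem and progenitor cells. Per the labels' protocols, genomic DNA was cut with MspI, an enzyme that cuts at CCGG whether or not the inner cytosine is methylated, so that fragments come mostly from CpG-rich DNA. Fragments were then ligated to methylated adapters, chosen by size on a gel, treated with bisulfite and amplified. Bisulfite turns unmethylated cytosine into uracil, which is read as T, and leaves methylated cytosine to be read as C. The submitters' processing notes name CASAVA version 1.7, Bismark and the mouse genome build mm9; the version of Bismark is not given in the sources used here.

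The authors deposited 1 table per library with a line for each CpG cytosine on each strand. Per the file headers, a line holds the chromosome, position and strand, the coverage and the frequency of C and of T. The coverage column holds whole read counts, and the deposited tables list only positions with a count of at least 10. The deposited C and T columns hold the percent of reads with each base; the 2 sum to between 90.1 and 100, the remainder being other bases. Methylated reads were computed as coverage times the percent of C, and unmethylated reads as coverage times the percent of T. Both products were whole numbers, within the rounding of the deposited percentages, at 100% of positions in each library. No step of duplicate removal or correction for incomplete conversion is given in the sources used here. PCR reads without molecular identifiers are not independent molecules, so all counting intervals below cover counting error only.

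Positions were joined over libraries by chromosome, position and strand. The main set held the 280635 autosomal CpG positions, out of 2371245 listed in any library, that had at least 10 reads in all 5 libraries, so that each library was measured over the same positions. Median coverage of this set was 60, 25 and 137 reads in knock-in replicates 1, 2 and 3 and 18 and 38 reads in wild-type replicates 1 and 2. Positions were grouped into tiles of 1 kb starting at multiples of 1000, and 24319 tiles with at least 3 such CpGs were tested. Their median number of reads was 384, 164 and 807 in the knock-in and 120 and 216 in the wild-type libraries. The methylation level of a tile or CpG is the percent of methylated among methylated and unmethylated reads. CpG density of a tile was the number of positions listed in any library, in classes of 3 to 9, 10 to 29 and 30 or more.

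Per-library levels were compared by an exact 2-sided permutation test of the difference of group means over the 10 ways to choose 3 of 5 libraries, for which the smallest possible p is 0.1. Tiles and CpG sites were tested with edgeR version 4.0.16 by its quasi-likelihood test on methylated and unmethylated read counts, with a term for each library, 3 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Alternatives were limma version 3.58.1 on arcsine square root levels, on the same after centring each library, and on log2 ratios of methylated to unmethylated reads with 1 read added to each. Fisher's exact test on pooled reads was a further alternative for CpG sites. Tiles were also counted where all knock-in libraries lay above both wild-type libraries, or all below, with group means at least 10 percentage points apart. These are called separated tiles. Fisher's exact test, 2-sided, compared separated and other selected tiles on each of 19 autosomes, and in windows of 10 Mb, with the rest of the autosomes. R version 4.3.3, Python version 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

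The statistics were tested on simulated data with the coverage, levels and spread between libraries of the 24319 real tiles and 200 changed tiles. Spread was estimated over all pairs of libraries, including pairs across the groups, so any difference between the groups enters it. A changed tile kept the spread estimated for its level before the shift, and tiles above 60% were not changed. With no change, edgeR and limma called 0 tiles. In tiles under 20%, edgeR recovered 0% of shifts of 10 or 20 points and 77% of shifts of 40 points. In tiles of 20 to 60%, it recovered 0% at 10 or 20 points and 7.5% at 40 points. For limma the corresponding shares in tiles under 20% were 0%, 51% and 82.5%, and in tiles of 20 to 60% they were 0%, 0% and 1%. The estimated spread beyond read counting in knock-in replicates 1, 2 and 3 was 0.0188, 0.0103 and 0.00516 at methylated fractions (not percent) of 0.001 to 0.01. At methylated fractions of 0.2 to 0.4 it was 0.0814, 0.24 and 0.0273. Shares recovered in tiles under 20% may therefore be too high.

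Groups, tests and most alternatives were fixed before the data were examined. The rule for named tiles was the 12 largest differences past the test in each direction or, where fewer than 5 passed, the 5 smallest p in each direction. Further tiles were named after their values were seen, by the distance between the nearest libraries of both groups, and are marked as such. The alternatives were a coverage minimum of 20 reads, leaving out positions in the top 0.1% of coverage, adding chromosome X, other tile sizes and CpG minimums, equal depth by thinning to 10 reads per CpG, both strands summed, read-weighted means, and leaving out each library. Promoters and lists of genes were planned but not analysed, since no mm9 annotation was used here and the gene table at hand is of another build. Regions are therefore named by mm9 coordinates, with no gene assigned, and Idh1 itself was not located.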

Results

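The question was whether DNA methylation in blood stem and progenitor cells differs between mice that carry the Idh1-R132H mutation and mice that do not. Idh1 encodes the cytosolic isocitrate dehydrogenase, and the R132H change recurs in glioma and acute myeloid leukaemia. The mutant enzyme makes 2-hydroxyglutarate, a metabolite that can inhibit the TET enzymes, which oxidise methylated cytosine. Methylation was read at single CpGs in LSK cells, which are lineage-negative, Sca1-positive and Kit-positive bone marrow cells, from a mixed 129Ola and C57Bl/6J background. There were 3 knock-in and 2 wild-type libraries. The labels do not say whether each came from a separate animal, so p-values measure at most the spread between these libraries, which may be technical.

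Depth differed widely. The tables listed 1208495, 697321 and 2028186 CpG positions for knock-in replicates 1, 2 and 3, and 447270 and 1131505 for wild-type replicates 1 and 2. Median coverage over these positions was 27, 18 and 33 reads in the knock-in libraries and 16 and 27 reads in the wild-type libraries. All comparisons below used the 280635 autosomal positions with at least 10 reads in each of the 5 libraries. Levels at these positions correlated between pairs of libraries with Pearson's r from 0.931 to 0.987 across CpGs, which are not independent replicates. The highest r was between knock-in replicate 3 and wild-type replicate 2, and the lowest between knock-in replicate 2 and wild-type replicate 1.

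Mean autosomal CpG methylation was 20.96% ± 0.364 (SD, n = 3) in knock-in and 20.3% ± 0.15 (SD, n = 2) in wild-type LSK cells. The difference was 0.692 percentage points, and each knock-in library lay above both wild-type libraries in these unweighted means. It was widest in CpGs of intermediate methylation, where levels have the most room to differ. Among the 13290 CpGs with a mean level of 20 to 80%, the level was 55.4% ± 1.97 (SD, n = 3) in knock-in against 50.0% ± 1.78 (SD, n = 2) in wild-type, a difference of 5.41 points. The 215256 CpGs under 20% had levels of 0.926% ± 0.105 (SD, n = 3) and 0.709% ± 0.121 (SD, n = 2). The 52089 CpGs at 80% or more had levels of 94.98% ± 1.33 (SD, n = 3) and 93.5% ± 0.171 (SD, n = 2). By exact 2-sided permutation, p was 0.2 for all CpGs, 0.1 for those under 20%, 0.2 for 20 to 80% and 0.3 for 80% or more, with adjusted values from 0.217 to 0.3 over a family of 13 comparisons. Since 10 divisions of the libraries allow no p under 0.1, no class could reach 0.05. An exact permutation p of 0.2 or more also means that another division differed by at least as much as the real groups. In mean tile levels, knock-in replicate 3 and both wild-type libraries differed from knock-in replicates 1 and 2 by -1.12 points. Knock-in minus wild-type was 0.949 points in the same tiles. Weighted by reads, the difference over all CpGs was 1.14 points (exact permutation p = 0.3), and the groups overlapped, with knock-in replicate 2 at 19.9% and wild-type replicate 1 at 20.1%. A single position, 98506661 on chromosome 2, at 95.7 to 97.2%, weighs heavily here. It held 683485 of 21660811, 102387 of 8996316 and 1051127 of 46817578 reads in knock-in replicates 1, 2 and 3. In wild-type replicates 1 and 2 it held 73602 of 6175131 and 282957 of 12986729 reads. Read-weighted levels were not computed without this position, so the 1.14 points and the order of the libraries apply with it included. The gap under 20% was 0.217 points, but 0.0428 when weighted by reads and 0.131 without wild-type replicate 1, and the gap at 80% or more was 1.45 points, but 0.790 without knock-in replicate 2. Over each library's own positions the difference was 9.79 points, where the libraries differ in which positions they list.

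**Figure D1:**
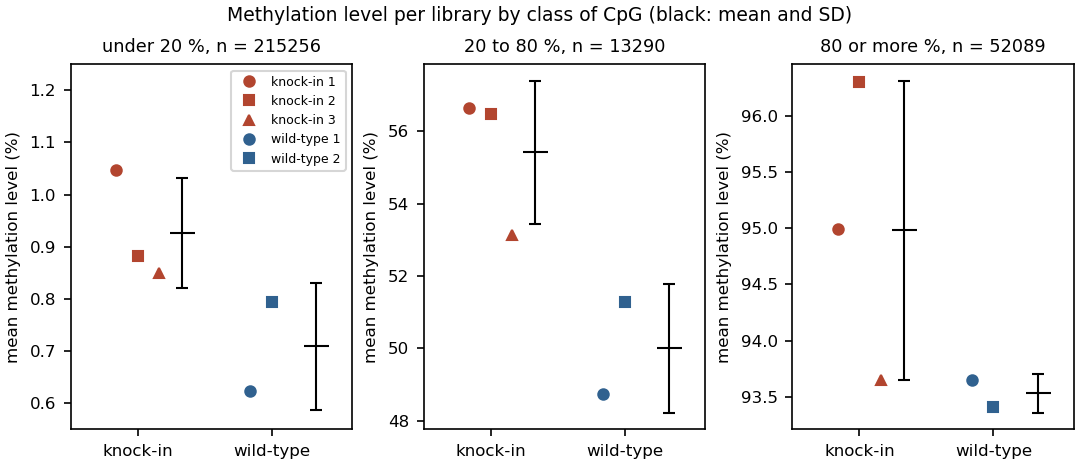
Mean methylation level in percent (vertical axes, which do not start at 0) of each library over CpGs with a 5-library mean under 20%, 20 to 80% and 80% or more; points are libraries and black marks are group means with SD. In the intermediate class the knock-in libraries read 56.6, 56.5 and 53.1% and the wild-type libraries 48.8 and 51.3%.

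CpG-dense regions were nearly unmethylated in both groups and CpG-poor regions highly methylated. The 11229 tiles of 1 kb with 30 or more listed CpG positions averaged 3.38% ± 0.189 (SD, n = 3) in knock-in and 3.02% ± 0.0866 (SD, n = 2) in wild-type. In the 7648 tiles with 10 to 29 positions the levels were 43.2% ± 0.732 (SD, n = 3) and 42.0% ± 0.196 (SD, n = 2), and in the 5442 tiles with 3 to 9 positions they were 78.9% ± 0.881 (SD, n = 3) and 77.1% ± 0.369 (SD, n = 2). The knock-in excess was 0.357, 1.24 and 1.77 points in order of falling density, each with an exact permutation p of 0.2. Weighted by reads, the differences were -0.00558, 3.54 and 2.26 points, so the order by density did not hold. Within tiles of intermediate level the excess was 4.88, 4.99 and 5.27 points, and without knock-in replicate 2 it was 2.97, 4.16 and 4.82 points; differences between density classes were not tested.

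Regions in which the groups did not overlap were mostly higher in knock-in cells. In 577 tiles all 3 knock-in libraries lay above both wild-type libraries with means at least 10 points apart, and in 151 tiles all lay below, a ratio of 3.82. Without the rule on size, 8.98% of tiles had knock-in above wild-type and 3.61% below, where chance, taken as the mean over all 10 divisions of the libraries, gives 6.40% and 7.47%. It is under 10% because 2 or more libraries have equal levels in 57.04% of tiles. Without this rule, 2 other divisions were more uneven than the real groups, whose ratio was 2.49: knock-in replicates 1 and 2 lay above the rest in 11.8% of tiles and below in 4.09% (ratio 2.88), and knock-in replicates 1 and 3 in 11.3% and 4.14% (ratio 2.72). Intermediate tiles held the highest share, with 218 of 1551 (14.1%) higher and 50 (3.22%) lower. Tiles near either end of the scale have less room for a difference of 10 points, and the other divisions were not counted by level class. Of the tiles at 80% or more, 275 of 7328 were higher and 83 lower, and of those under 20%, 84 of 15440 were higher and 18 lower. The ratio was 3.30, 4.51 and 4.5 in tiles of 3 to 9, 10 to 29 and 30 or more positions. Of the 9 other divisions of the libraries into 3 and 2, the one that set knock-in replicates 1 and 2 against the rest gave the most uneven counts, 713 tiles higher in these 2 and 229 lower, a ratio of 3.11. Without knock-in replicate 1 the ratio of the real groups was 2.31, from 798 and 345 tiles.

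**Figure D2:**
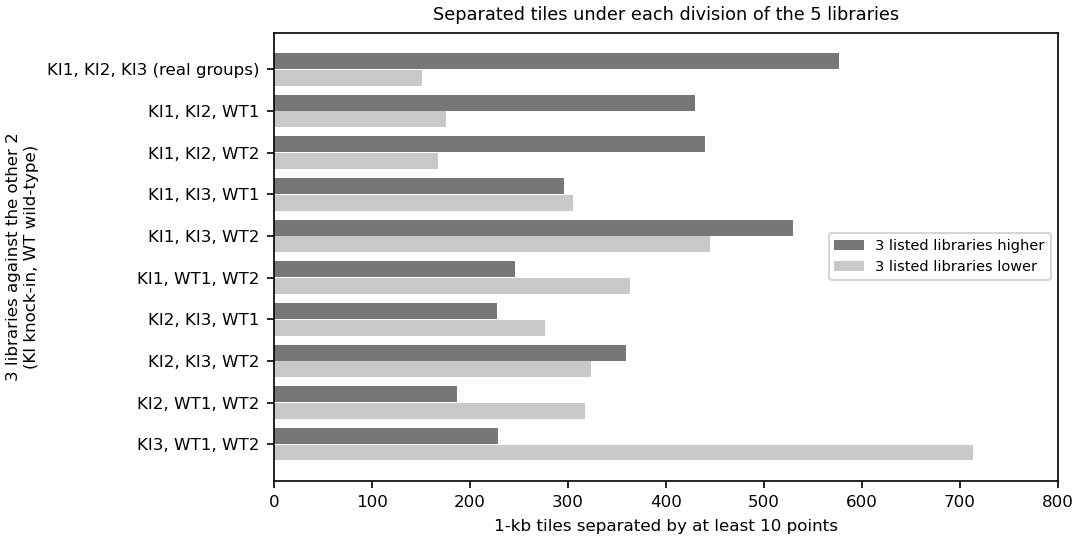
Number of 1-kb tiles (horizontal axis) separated by at least 10 points for each division of the 5 libraries into 3 (listed on the vertical axis) and 2; dark bars count tiles in which the 3 listed libraries were higher, light bars those in which they were lower. The real groups gave 577 and 151 tiles, and knock-in replicates 1 and 2 lay above the other libraries in 713 tiles and below in 229.

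The tiles with the widest distance between the nearest libraries of both groups, chosen after their values were seen, rested on few CpGs. On chromosome 5, the tile from 130845000 to 130845999 (mm9, 5 CpGs, 55 to 549 reads per library) was methylated at 77.0% ± 3.46 (SD, n = 3) in knock-in and 37.99% ± 9.91 (SD, n = 2) in wild-type cells. The tile on chromosome 2 from 156530000 to 156530999 had 93.8% ± 1.62 (SD, n = 3) and 59.8% ± 6.41 (SD, n = 2), over 4 CpGs and 56 to 370 reads. That on chromosome 8 from 48938000 to 48938999 had 89.1% ± 3.76 (SD, n = 3) and 54.2% ± 9.11 (SD, n = 2), and that on chromosome 19 from 41113000 to 41113999 had 28.1% ± 2.72 (SD, n = 3) and 3.14% ± 1.701 (SD, n = 2). Further tiles of this kind began at 34520000 on chromosome 1, 26453000 on chromosome 14, 29580000 on chromosome 7 and 4298000 on chromosome 19. These 8 tiles differed by 24.9 to 39.0 points and rested on 3 to 5 CpGs each. The 4 widest in the other direction began at 120476000 on chromosome 12, 129262000 on chromosome 4, 97847000 on chromosome 11 and 88898000 on chromosome 15. The first of these was at 9.53% ± 8.69 (SD, n = 3) in knock-in and 43.9% ± 1.44 (SD, n = 2) in wild-type cells, and the last at 51.0% ± 0.673 (SD, n = 3) and 69.3% ± 4.08 (SD, n = 2). Counting only tiles with at least 10 points between the nearest libraries, 76 were higher and 9 lower, a ratio of 8.44 that was 3.42 to 6.28 with a library left out and lowest without knock-in replicate 2. The division of knock-in replicates 1 and 2 against the rest gave 182 and 28 such tiles, and that of knock-in replicate 2 and wild-type replicate 1 against the rest gave 104 higher and 148 lower.

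Among the 8437 tiles with at least 10 shared CpGs, 25 were separated with knock-in higher and 3 with knock-in lower. The widest was on chromosome 5 from 111847000 to 111847999, with 18 CpGs and 399 to 2938 reads per library, at 53.4% ± 15.4 (SD, n = 3) in knock-in and 19.3% ± 4.62 (SD, n = 2) in wild-type. A tile on chromosome 7 from 148668000 to 148668999 with 35 CpGs was at 23.4% ± 1.596 (SD, n = 3) and 12.6% ± 0.710 (SD, n = 2), over 456 to 4837 reads; the difference of 10.8 points was 4.29 at 10 reads per CpG and 1.13 over its CpGs with at least 20 reads. A tile on chromosome 2 from 24261000 to 24261999 with 11 CpGs was at 25.3% ± 0.339 (SD, n = 3) and 8.81% ± 5.12 (SD, n = 2). The 3 tiles with lower levels began at 72410000 and 11009000 on chromosome 8 and at 137279000 on chromosome 4; the tile at 11009000 rests on wild-type replicate 1, without which its difference went from -10.9 to -0.164 points, and that at 72410000 went from -14.5 to -5.54 points without the same library. The tile at 137279000 went from -12.1 to -7.09 points without knock-in replicate 1.

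**Figure D3:**
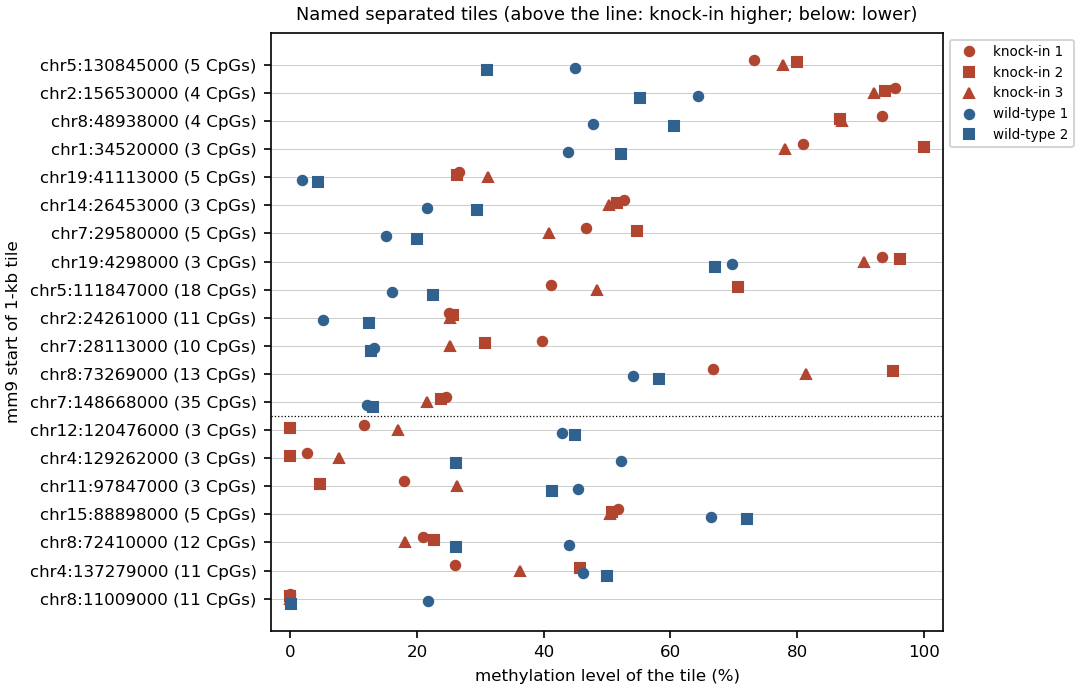
Methylation level in percent (horizontal axis) of each library in the named separated tiles, listed by chromosome and mm9 start with their number of CpGs; red points are knock-in and blue points wild-type libraries, and the dotted line parts tiles with knock-in higher (above) from those with knock-in lower (below). The nearest libraries of both groups lie 28.2 points apart in the top tile and 0.141 points apart in the bottom tile, which rests on wild-type replicate 1.

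No tile passed the test across all tiles. With edgeR's quasi-likelihood test, 0 of 24319 tiles were higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.80. The spread of the simulated data was estimated over all pairs of libraries, including pairs across the groups. A real difference between the groups would enter it, so simulated shares are not a clean measure of no change. At an unadjusted p under 0.05 there were 205 higher and 182 lower tiles, 1.59% of all, against 2.27% in simulated data without change. These counts moved when 1 library was left out, to 55 and 128 without wild-type replicate 1, 100 and 89 without knock-in replicate 1, 181 and 241 without wild-type replicate 2 and 267 and 48 without knock-in replicate 3. By limma, 0 tiles passed on arcsine levels (733 higher and 307 lower at unadjusted p under 0.05), 0 after centring each library (813 and 295) and 0 on log2 ratios (633 and 404). On arcsine levels the unadjusted share was 4.28% of tiles, against 4.97% in simulated data without change. The smallest unadjusted edgeR p, 3.29e-05, was found on chromosome 13 from 58120000 to 58120999, where all knock-in libraries read 100% over 4 CpGs and the wild-type libraries 76.5 and 89.0%. The next 4 higher tiles by p began at 97806000 on chromosome 11, 183772000 and 135960000 on chromosome 1 and 30328000 on chromosome 2, and the 5 lower ones at 133574000 on chromosome 4, 38409000 on chromosome 7, 76815000 on chromosome 14, 68353000 on chromosome 17 and 113839000 on chromosome 2. These 9 tiles had an edgeR adjusted p of 1, and in each of them 1 group was at or near 0 or 100%. Several rest on 1 library: the difference at 97806000 went from 25.4 to 5.65 points and that at 68353000 from -7.35 to -0.189 without wild-type replicate 1, and that at 135960000 from 24.1 to 9.06 without knock-in replicate 2. The 8 and 4 tiles chosen by distance had unadjusted edgeR p from 0.0316 to 0.472. In simulated data of the same depth, changed tiles lay under 60% and kept the spread of their level before the shift. There edgeR recovered 0% of shifts of 20 points, so differences of that size were not detectable tile by tile with it under 60%. Shifts in tiles above 60% were not simulated, and any difference between the groups within the simulated spread may lower the shares recovered. For limma the share recovered was 51% in tiles under 20%, which may be too high, and 0% in tiles of 20 to 60%.

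Among single CpGs, 1 of 280635 was higher in knock-in and 0 were lower by edgeR at an adjusted p under 0.05, against 564 and 183 (0.266% of sites) at an unadjusted p under 0.05. The latter were 70 and 36 without knock-in replicate 1, 164 and 36 without knock-in replicate 2, 37 and 6 without knock-in replicate 3, 200 and 166 without wild-type replicate 1 and 983 and 776 without wild-type replicate 2. The 1 site, with an edgeR adjusted p of 8.7e-40 and named after its values were seen, is at position 98506661 on chromosome 2, where 73602 to 1051127 reads per library were listed. Its level was 97.2, 96.7 and 96.5% in the knock-in libraries and 95.7 and 96.2% in the wild-type libraries. The knock-in levels spread further than the distance between the nearest libraries of both groups. The edgeR p of this very deep position therefore does not measure the spread between libraries. No site passed by limma on arcsine levels, where the smallest adjusted p was 0.654. At an unadjusted p under 0.05 limma picked 6170 higher and 3637 lower sites. These are 3.5% of sites. Sites without change were not simulated, so the share that no change would give is not known. Fisher's exact test on pooled reads, which ignores the spread between libraries, called 5840 sites higher and 2884 lower. With 20 reads required, or with positions in the top 0.1% of coverage left out, edgeR called 0 sites higher, and without wild-type replicate 2 it called 3.

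The distribution over chromosomes was examined because a segment of one parental strain can stay linked to a knock-in locus, here on chromosome 1. With 0 called tiles the planned comparison could not be made. Chromosome 1 held 3 of the 36 tiles with an unadjusted p under 0.01, out of 1408 tested (odds ratio 1.48, 95% interval 0.565 to 5.12, Fisher's exact p = 0.463, adjusted p = 1). None of the 19 autosomes and none of the 243 windows of 10 Mb passed for these tiles, and none of the 257 windows for CpG sites at the same limit. With only 36 tiles and 17 sites selected, these comparisons could detect little. Separated tiles were compared after the results were seen. Chromosome 1 held 42 of them among 1408 tested tiles (2.98%), against 2.99% on the other autosomes (odds ratio 0.996, 95% interval 0.735 to 1.38).

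The 27 CpGs of mitochondrial DNA shared by all libraries gave the background of unconverted cytosine. In the knock-in libraries 0.143% (20 of 14030 reads, 95% Wilson interval 0.0923 to 0.220), 0.0363% (3 of 8263, interval 0.0123 to 0.107) and 0.0431% (27 of 62670, interval 0.0296 to 0.0627) of reads were methylated. In the wild-type libraries the shares were 0.198% (14 of 7058, interval 0.118 to 0.333) and 0.0946% (14 of 14797, interval 0.0564 to 0.159).

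Chromosome X, which was kept out of these comparisons by plan, parted the libraries into 2 kinds. Over 159 CpG-dense tiles on chromosome X, with 30 or more listed positions, the mean level was 24.1% in knock-in replicate 2 and 24.1% in wild-type replicate 1. It was 2.94, 3.82 and 3.65% in knock-in replicates 1 and 3 and wild-type replicate 2. Dense autosomal tiles were at 2.96 to 3.53% in all 5 libraries. The sex of the animals is not in the labels.

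**Figure D4:**
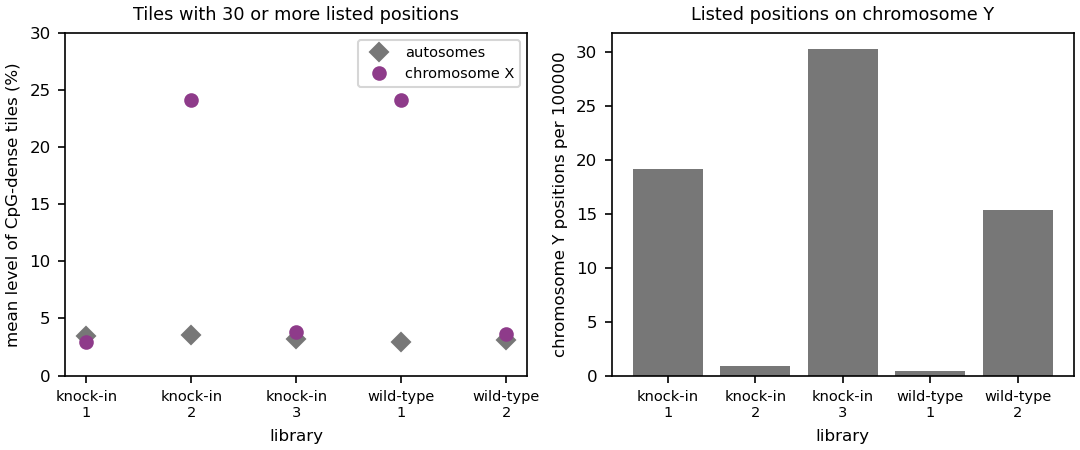
Left, mean methylation level in percent of CpG-dense tiles on autosomes (grey) and on chromosome X (purple) for each library; right, number of listed chromosome Y positions per 100000 listed positions. Knock-in replicate 2 and wild-type replicate 1 stood at 24.1% on chromosome X and listed 0.860 and 0.447 chromosome Y positions per 100000, against 15.4 to 30.3 in the other 3 libraries.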

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

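Re-chosen CpGs, equal depth for the overall level, the distance of 10 points between nearest libraries, the covariate for the chromosome X class and separated tiles by chromosome were tests chosen after the results were seen; the others were planned. Over own CpGs the overall difference was 9.79, but there the libraries differ in which positions they list, so the comparison is not like for like. Over shared CpGs the difference stayed above 0, from 0.518 with 20 reads to 1.14 weighted by reads. It was 0.560 to 0.900 with a library left out. Leaving out a library could not change its sign, since the groups did not overlap in the unweighted means. The difference was 0.571 over CpGs re-chosen without both shallow libraries, knock-in replicate 2 and wild-type replicate 1. Read-weighted differences of the tile classes were -0.00558, 3.54 and 2.26 in order of falling density, against 0.357, 1.24 and 1.77, and the cause was not tested. edgeR called 0 tiles in either direction under each alternative that was run. limma was run on the main tiles only and called 0 in each of its forms. In simulated data edgeR recovered 0% of shifts of 10 or 20 points in tiles under 60%. Its counts of 0 therefore say little about shifts of that size. Higher CpG sites numbered 0 with 20 reads, 0 without the top 0.1% of coverage, which removes the called site, 0 by limma arcsine, 0 by limma after centring, and 1 to 3 with a library left out. Pooled Fisher's tests gave 5840 higher and 2884 lower sites, since they ignore spread between libraries. Lower sites numbered 0 with any library left out. Separated tiles with knock-in higher and lower numbered 105 and 25 with 20 reads, 2042 and 550 with at least 1 CpG, 25 and 3 with at least 10 CpGs, and 76 and 9 with 10 points between nearest libraries. They numbered 1727 and 563 re-chosen without wild-type replicate 1 and 3666 and 1527 without both shallow libraries. With a library left out they ranged from 661 to 1707 and from 205 to 640, since fewer libraries must then be separated. The ratio of higher to lower was 8.33 with at least 10 CpGs and 8.44 with 10 points between nearest libraries, where it was 5.03 at equal depth and 3.42 to 6.28 with a library left out. Under the main rule it was 2.40 without both shallow libraries and 2.31 to 3.24 with a library left out, and the lowest came without knock-in replicate 1. The cause of these shifts in ratio was not tested. None of the 220 alternative values of the 30 named tiles changed sign, but 18 values, in 15 tiles, were over 1.5 times smaller, down to -0.164 from -10.9 at 11009000 on chromosome 8 without wild-type replicate 1, and 9 were over 1.5 times larger. Where a library was left out the sign could not change, since the groups do not overlap in any named tile. Where a single wild-type library was left, it was assumed to vary as the knock-in libraries do. Promoters and gene lists were not run, since no mm9 annotation was used here. Depth limits single tiles most in knock-in replicate 2 and wild-type replicate 1, with medians of 164 and 120 reads per tile.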

Other observations

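The tests of explanations and the windows in this part were chosen only after the result was seen, except the count of separated tiles after thinning, which was planned like the values by library. Separated tiles were spread over the genome with 1 exception. The window from 1 to 10000000 on chromosome 8 (mm9) held 8 of them among 50 tested tiles (16%), against 2.97% elsewhere (Fisher's exact p = 1.1e-04, adjusted p = 0.0266 over 243 windows). Of the 8, 7 were higher in knock-in and 1 lower, all between 3392000 and 5639999. The widest was the tile from 3392000 to 3392999, at 64.0% ± 6.89 (SD, n = 3) in knock-in and 29.8% ± 9.30 (SD, n = 2) in wild-type over 6 CpGs. Neighbouring tiles are not independent, which Fisher's exact test ignores. None of the 19 autosomes as a whole passed, with a smallest adjusted p of 0.148.

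The higher chromosome X level of knock-in replicate 2 and wild-type replicate 1 was weighed against their low depth, as they are also the shallowest libraries. After thinning each library to 10 reads per CpG, the nearest libraries of both kinds still lay 15.7 points apart over 3775 shared X positions, which argues against depth. In female cells CpG islands on the inactive X chromosome are methylated, and the highest chromosome Y rate of these 2 libraries was 0.0560 of the lowest rate of the others, in line with female donors for both, as a hypothesis. Each group then holds both sexes, and with the chromosome X class as a covariate edgeR called 0 tiles (214 higher and 125 lower at unadjusted p under 0.05).

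More tiles were separated upward than downward in knock-in cells, at a ratio of 3.82. Incomplete bisulfite conversion of whole knock-in libraries is argued against by mitochondrial CpGs, with an upper 95% bound of at most 0.220% methylated reads where separated tiles differ by at least 10 points. Their knock-in minus wild-type difference of -0.0725 points, at most 0.0425 by the bounds, also lies below the excess of 0.392 points in tiles under 20%, while the read-weighted excess of 0.0334 is under that bound and is not settled by it. Unequal depth is argued against by a ratio of 3.88 after thinning, while few molecules in the 2 shallowest libraries stay open: the other 3 libraries gave 2.40, but knock-in replicate 1 against the other 2 of them also gave 1.78 (4805 tiles higher and 2696 lower). An effect of the genotype may be one source, as may differences between libraries of any origin: 10 divisions are too few for a share under 0.05, with 3.82 for the real groups and 3.11 for the highest other under the 10-point rule, and 2.49 and 2.88 without it.

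At an unadjusted p under 0.05, edgeR picked 387 tiles for the real groups, the fewest of the 10 divisions, and 424 to 1436 for the other 9; limma on arcsine levels picked 1040 for the real groups and 845 to 2351 for the others. Knock-in replicates 1 and 2 against the rest gave 1436 by edgeR, and knock-in replicate 2 and wild-type replicate 1 against the rest gave 1352. Whether a shared structure of these libraries or their unequal spread gave the higher counts was not tested. At an adjusted p under 0.05, 1 of the other divisions, knock-in replicate 1 and wild-type replicate 1 against the rest, had 1 tile and the real groups had 0. Spread beyond read counting also differed by library. In tiles with levels of 40 to 60%, the overdispersion (0 where levels differ only by read counting) was 0.0825, 0.221 and 0.0401 in the knock-in and 0.106 and 0.0402 in the wild-type libraries. It was estimated from squared differences in level over all pairs of libraries, including pairs across the groups. Differences of any origin between libraries enter it, so it does not measure copied reads alone.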
